A study of Homo sapiens with 12 samples.

How the data were processed

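Total RNA of A431 cells was isolated with a commercial kit and checked for integrity, and biotin-labelled cRNA was made from 100 ng of it, per the labels' protocols. The 12 samples were hybridised to 12 positions of one Illumina expression chip; the positions ran with the time label and alternated between the groups. The deposited table holds intensity values per probe, the mean brightness of its beads, per the file headers; no background had been subtracted, since the lowest value on an array lay between 61.0 and 65.9, and medians ranged from 74.6 to 79.2. The same deposited table gives a detection p-value per probe and array, in steps of 1 in 770. The authors' second file holds processed values of the same arrays; its scale is not stated, and set against the raw signals it behaves as log2 values that were quantile-normalised and not centred. Its columns share 1 distribution (largest difference between arrays 0.00866, median of every array 3.82), and each of the 12 columns correlated best with the raw signal of its own array (r between 0.947 and 0.970). Which background step the authors used on these log2 values is not given in the sources used here. The package lumi is named in the submitters' processing notes without version or role.

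Samples were grouped by the titles, 6 resistant and 6 sensitive, with 1 array per group at each time label from 30 to 35. No pair of arrays held identical values. No genome build is given in the sources used here, so no coordinates are printed. Gene names came from the file's own symbols: 44053 of 47323 probes carried a symbol and 3270 did not, and no probe carried several. Symbols of 35672 probes were matched by Entrez identifier to the RefSeq gene table of GRCh38.p14, which changed the symbol of 8790 probes; the other names were kept. The table was otherwise used only for the order of neighbouring genes.

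Intensities were background-corrected and normalised with neqc in limma 3.58.1 under R 4.3.3: normexp with the negative control distribution inferred from the detection p-values, an offset of 16, quantile normalisation and log2. Differences are therefore on this log2 scale, which understates the change of dim genes. A gene was represented by its probe with the highest mean over the arrays, among probes detected at p under 0.01 on at least 3 arrays, which left 12495 genes; 2921 genes had several detected probes. Among the 143 genes that the naming rule picked for the comparison of the groups, 47 had several detected probes, and these disagreed in sign only for CD58, which did not pass the threshold. In size they could differ widely. The differences ran from 0.72 to 3.13 for COXFA4L3, from 0.82 to 3.04 for CSAG3 and from 1.79 to 3.03 for CCL5. For CCT6P1 they ran from -2.28 to -0.54. A printed size therefore belongs to the chosen probe. Where a gene past the threshold was detected on at most 2 arrays of a group, or its mean in a group lay under the mean of the lowest detected signals, 4.55, the difference is given as a lower bound (at least N-fold). For it, values under the lowest detected signal of their array were raised to that signal before the means were taken. The bound is that of the chosen probe, and another detected probe of the gene can differ by less.

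Before the data were examined, the tests, the gene lists and the rule for naming genes were fixed. Resistant and sensitive arrays were compared with lmFit and eBayes without covariates. Trends were fitted as a slope on the time label (centred at 32.5) within each group, in a joint fit over the 12 arrays, and the slope difference was a contrast of that fit. P-values were adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. EGFR was also tested by a two-sided exact permutation test. The 29 lists were tested two-sided with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way. Among the lists, 2 hold markers of NK cells and leukocytes, the other cells that the cultures could hold. Named between the groups were the 12 highest and 12 lowest differences past the threshold without overlap between the groups; for each trend, the 6 highest and 6 lowest slopes past the threshold; up to 4 members of a list with the lowest adjusted p; and a fixed set of genes of EGFR signalling, NK cell recognition, cell death, antigen presentation and interferon response. Genes with provisional names or open reading frames were skipped. The neighbours of EGFR and the windows along chromosomes were chosen after seeing the data.

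Arrays that share a time label deviated together from their group means: the correlation of their deviations over genes was between 0.116 and 0.396 at the 6 time labels. At C30, C32 and C34 the resistant array was best matched by the sensitive array of its own label. At C31, C33 and C35 it was not, so the time label pairs the arrays only in part. The source of this pairing may be the time itself or the adjacent chip positions. The blocked fit is an alternative.

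The scripts were tested on simulated data with the real means of the 12495 genes, with 100 genes changed at each of 2 sizes. The spreads were those left by the slope fit, the same in both groups and independent between genes. Between the groups, 86% of changes of 0.5 log2 units and 100% of changes of 1 were recovered, with 8 false calls. For slopes of 0.2 and 0.4 per time label, 78% and 98% were recovered in resistant cells and 79% and 97% in sensitive cells; for slope differences of these sizes, 42% and 96%. A shift of 0.5 in the interferon list was called by camera, with no other list. Real genes of this list moved together (estimated correlation 0.77), and the real comparison of the groups keeps the trends in its spread. The shares and the list result therefore check the scripts and do not carry over to these data.

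The alternatives were median scaling in place of quantile normalisation, no background correction, an offset of 50, the authors' processed values, no filter or detection on all 12 arrays, the mean of a gene's probes, an intensity-dependent robust prior, array weights, the time label as a block or as a linear term, early (C30 to C32) or late (C33 to C35) time labels only, each array left out in turn, each EGFR probe, and the other list tests. Leaving out the resistant C30 and C31 arrays was added after seeing the data. Windows of 7 neighbouring genes were scanned with zoo 1.8.14 and compared with 1000 shuffles of the genes. Figures were drawn with matplotlib 3.10.9.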

Results

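Gene expression was measured in A431, a human epidermoid carcinoma cell line known for its high level of the epidermal growth factor receptor (EGFR), on 12 Illumina bead arrays of a single chip. Of these, 6 arrays held RNA of cells labelled resistant to antibody-dependent cellular cytotoxicity (ADCC), the killing of antibody-coated cells by cells that carry an Fc receptor. According to the series description, such cells had been kept under continuous exposure to effector cells and cetuximab, an antibody against EGFR. The effector cells were NK92-CD16V, a natural killer (NK) cell line with an Fc receptor that is described as lacking killer inhibitory receptors (KIR). The other 6 arrays held control cells labelled sensitive. Each group had 1 array at each of the 6 time labels from C30 to C35, whose letter the labels do not explain. The time labels of a group served as its replicates, and since nothing in the labels says that they were separate cultures, the p-values measure the spread between these samples, which may be technical. Between 14648 and 15987 of the 47323 probes were detected on an array, and 12495 genes were tested. The number of arrays, 6 per group, limits the precision. Over the probes detected on at least 3 arrays, correlations of log2 intensity lay between 0.989 and 0.995 within the sensitive group, between 0.973 and 0.994 within the resistant group and between 0.949 and 0.982 across groups.

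The antigen of cetuximab was measured first. EGFR, the receptor tyrosine kinase on chromosome 7 to which the antibody binds, fell by 3.95 log2 units (SE 0.14) in the resistant cells, a 15.4-fold difference. Its normalised log2 intensity was 6.71 ± 0.39 (SD, n = 6) in resistant cells and 10.66 ± 0.08 (SD, n = 6) in sensitive cells (limma, adjusted p = 1.02e-11), and the transcript was still detected on all 6 resistant arrays. Of the 4 EGFR probes on the array, 3 were lower in resistant cells without overlap between the groups, with a difference of -3.95 for the probe designed on NM_005228.3, of -5.45 for NM_201283.1, detected on 5 of the 6 resistant arrays, and at least 3.60-fold for NM_201284.1. For each of these, the two-sided exact permutation test gave p = 0.00216, the smallest value that 6 against 6 arrays can give. The probe for NM_201284.1 was not detected on any resistant array, so its difference is a lower bound. The remaining probe, for NM_201282.1, was not detected on any array and differed by -0.06 (exact permutation p = 0.0563). Among the relatives of EGFR, ERBB3 rose by 0.84 (adjusted p = 5.74e-05) and ERBB2 by 0.39 (adjusted p = 0.0235), while NRG1, a ligand of ERBB3, fell by 0.72. The differences of the 3 detected ERBB3 probes ran from 0.19 to 0.84, so its size is uncertain. Over the list of ERBB receptors and ligands, 3 of the 12 measured genes rose and 2 fell. The list as a whole was not past the threshold (camera adjusted p = 0.936), and its mean of -0.23, its median of 0.11 and the upward direction of camera did not share a sign.

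The genes that follow EGFR on chromosome 7 fell as well. In the order of the reference annotation GRCh38.p14, EGFR belonged to an unbroken run of 12 measured protein-coding genes, from SEC61G to VKORC1L1, that all fell in resistant cells. Of these, 9 fell by at least 1 log2 unit: EGFR itself, LANCL2 (-3.67), VOPP1 (-1.51), MRPS17 (-2.58), NIPSNAP2 (-1.59), PSPH (-2.93), CCT6A (-2.13), SUMF2 (-1.94) and CHCHD2 (-1.63). On the other side of the run, GRB10 (-0.12, adjusted p = 0.447) and FIGNL1 (-0.11, adjusted p = 0.337) were not past the threshold, and of the next genes UPP1 fell (-0.62), while TNS3 (0.88) and IGFBP3 (1.86) rose. This run was singled out after its values had been seen.

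**Figure D1:**
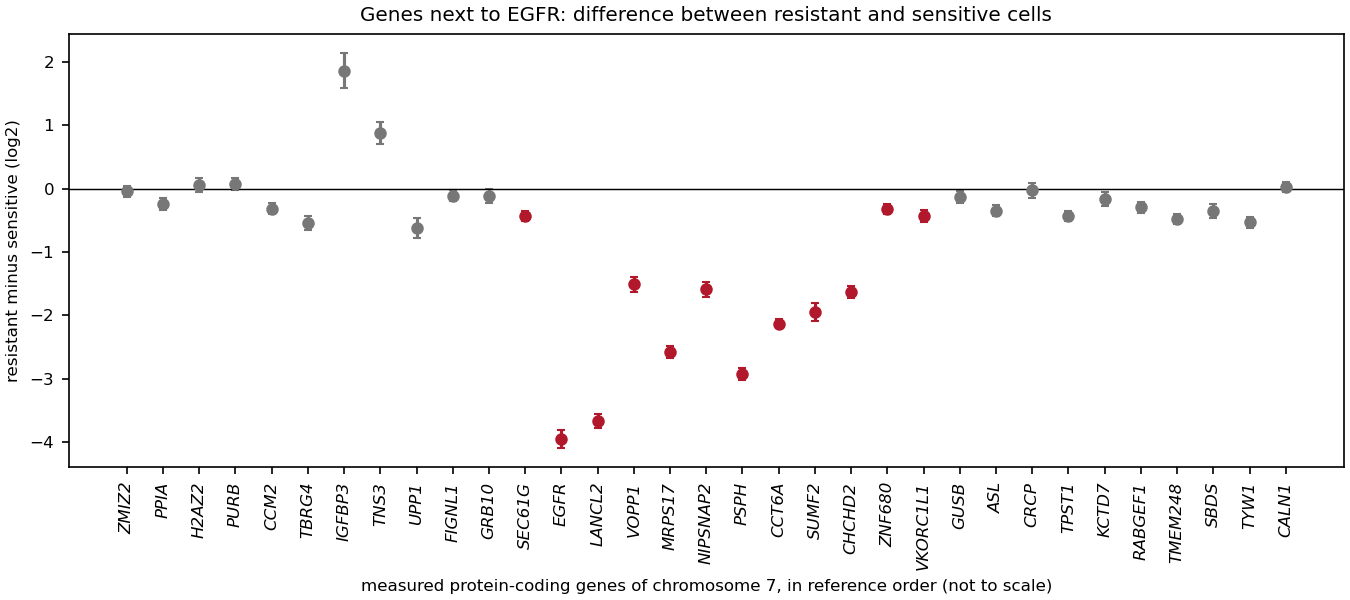
Difference in normalised log2 intensity, resistant minus sensitive, for 33 measured protein-coding genes around EGFR in reference order, with bars of 1 SE from limma; distances between genes are not to scale. Red points mark the unbroken run of 12 genes that fell, with a median of -1.79; the other genes are grey.

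Resistant and sensitive cells differed widely. Of the 12495 genes tested, 3905 passed the threshold (limma, adjusted p under 0.05), with 1981 higher and 1924 lower in resistant cells. The share that was higher was 50.7%, and 45.7% with median scaling. An absolute log2 difference of at least 1 was reached by 283 of them, of which 194 were higher and 89 lower. The 6 resistant and 6 sensitive values did not overlap for 2021 genes, or 16.2%, where chance would give 0.216%. The 12 genes with the highest log2 differences included CD74, the invariant chain of MHC class II, which was not detected on any sensitive array and was at least 10.3-fold higher in resistant cells, and CLIC3, an intracellular chloride channel protein, which was detected on 1 of the 6 sensitive arrays and was at least 9.98-fold higher. CD24, a glycosylated surface protein, was higher by 3.43 (SE 0.13), with values of 9.50 ± 0.25 in resistant and 6.08 ± 0.24 in sensitive cells (SD, n = 6 each). The interferon-induced GTPase GBP4 was higher by 3.24, COXFA4L3 by 3.13, the chemokine CCL5 by 3.03 and the cytokine IL32 by 2.96. GBP4 and IL32 were detected on 5 and COXFA4L3 on 4 of the 6 sensitive arrays. CSAG3, a cancer-testis antigen, was not detected on any sensitive array and was at least 6.54-fold higher. PLAAT4 (2.92), the interferon-induced genes IFI27 (2.75) and OASL (2.69) and the histone gene H2BC5 (2.64) were the others. The order among the 12 is uncertain where a gene is given as a lower bound or where its probes differed in size. Examples are COXFA4L3 (0.72 and 3.13) and CD24 (1.75 and 3.43). The lower bounds are those of the chosen probe. Other detected probes differed by 2.83 for CD74 and by as little as 0.82 for CSAG3, less than the bounds. For IFI27, 1 of the sensitive arrays (C32) stood at 9.26, above the other 5, which lay between 7.79 and 7.87.

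Among the 12 lowest genes, HSPB1, a small heat shock protein, stood at 9.54 ± 0.14 (SD, n = 6) in sensitive cells, was detected on only 2 of the 6 resistant arrays and was at least 25.03-fold lower in resistant cells. PPARGC1A, a coactivator of mitochondrial biogenesis, was detected on 1 resistant array and was at least 11.6-fold lower in resistant cells. SGCE, a sarcoglycan, was at least 5.86-fold lower and PADI3, an enzyme that citrullinates proteins of the hair follicle, at least 4.33-fold lower; each was detected on 2 resistant arrays. Besides EGFR and its neighbours LANCL2, PSPH, MRPS17 and CCT6A, the 12 lowest held the pseudogenes CHCHD2P2 (-2.41), CCT6P1 (-2.28) and CHCHD2P9 (-2.14). These resemble CHCHD2 and CCT6A, so their probes may read the parent genes and their identity is uncertain. Of these 12 genes, 8 carried chromosome 7 in the deposited probe annotation. When only the 6 arrays of C33 to C35 were used, 2280 genes passed the threshold; with the resistant C30 and C31 arrays left out, a choice made after seeing the data, the count was 3527.

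**Figure D2:**
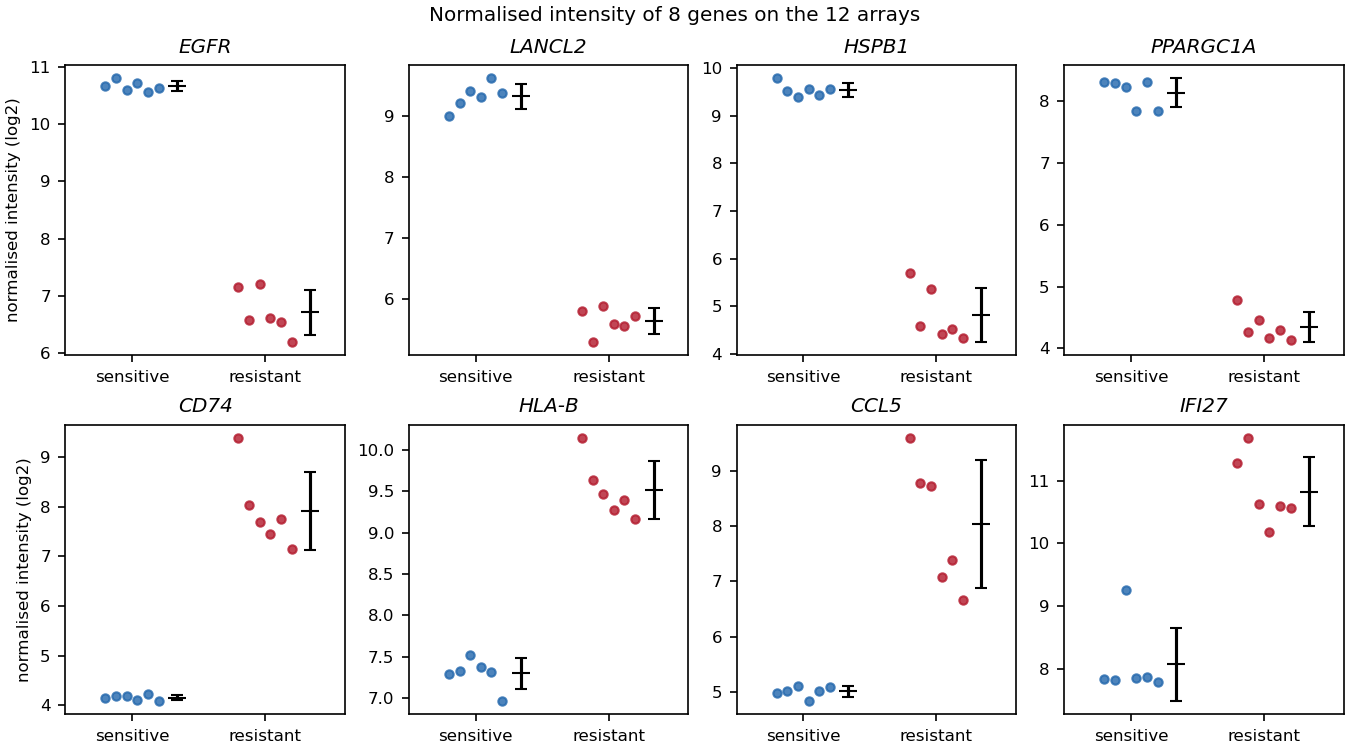
Normalised log2 intensity of 8 genes on each of the 12 arrays; points are arrays in the order C30 to C35 from left to right within a group, and the black marks give the mean and SD of 6 arrays. EGFR, LANCL2, HSPB1 and PPARGC1A were lower and CD74, HLA-B, CCL5 and IFI27 higher in resistant cells, without overlap; EGFR stood at 6.71 against 10.66.

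Lists of genes fixed before the data were examined showed which groups moved together. Of 29 lists, 16 passed camera with its preset correlation of 0.01, with 12 shifted up and 4 down in resistant cells; fry called 22. None of the 29 passed with an estimated correlation (lowest adjusted p = 0.175), and the value is given with each list. Interferon-stimulated genes, the antiviral programme, rose by a mean of 1.19: 36 of 44 measured members rose and 0 fell (39 rose when adjusted over the list alone). The examples were HERC5 (2.26), MX1 (2.43), ISG20 (1.81) and ISG15 (1.92) (camera adjusted p = 6.64e-14; adjusted p = 0.303 with an estimated correlation). Among interferon gamma-induced genes, 10 of 16 rose and 0 fell (11 rose adjusted over the list alone), such as CD74, GBP4 and GBP2 (2.42), and IRF1 rose by 0.94 (camera adjusted p = 1.34e-05; adjusted p = 0.303 with an estimated correlation).

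Genes of MHC class I antigen presentation, the ligands and loading machinery that NK and T cells inspect, rose in 14 of 20 cases and fell in 2 (15 and 3 adjusted over the list alone). HLA-B rose by 2.22, from 7.30 ± 0.18 to 9.51 ± 0.35 (SD, n = 6 each), HLA-F by 1.49, HLA-C by 0.62 and B2M, the shared light chain, by 1.20 (list, camera adjusted p = 3.00e-06; adjusted p = 0.255 with an estimated correlation). The ligands of NK cell receptors were not past the threshold as a list (camera adjusted p = 0.122), and 3 of 12 rose: ULBP2 (1.06) and RAET1G (1.01), ligands of the activating receptor NKG2D, and HLA-E (0.85), the ligand of the inhibitory receptor NKG2A. MICA differed by -0.31 (adjusted p = 0.0602), MICB by 0.19 (adjusted p = 0.121), PVR by -0.05 (adjusted p = 0.828) and CD58 by -0.02 (adjusted p = 0.894). Of the leukocyte adhesion molecules, 5 of 14 rose and 1 fell (6 and 1 adjusted over the list alone), with CEACAM1 at least 2.54-fold higher (detected on 1 sensitive array), CD47 at 0.82 and CD99 at 0.62 (camera adjusted p = 0.0416; adjusted p = 0.175 with an estimated correlation). The bound for CEACAM1 is that of the chosen probe, and its other detected probe differed by only 0.75. ICAM1, the ligand of leukocyte integrin LFA-1, differed by -0.14 (adjusted p = 0.210). Of the immune checkpoint ligands, 5 of 14 rose and 1 fell, with LGALS1 at 0.74 and NT5E at -1.10 (camera adjusted p = 0.0435; adjusted p = 0.255 with an estimated correlation); CD274 was not detected on any array.

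Inflammatory and epidermal genes also moved. Of the NF-kB and inflammatory cytokine genes, 15 of 28 rose and 2 fell, with IL32, SAA1 (2.26) and TNIP1 (0.81) higher and IL1B (-1.26) lower (camera adjusted p = 3.43e-05; adjusted p = 0.175 with an estimated correlation). Epidermal differentiation genes rose in 13 of 18 cases (15 adjusted over the list alone), among them the keratin KRT17 (2.50) and the kallikrein KLK5 (1.18), while KRT16 (at least 2.70-fold higher) and KLK10 (at least 1.82-fold higher) were not detected on any sensitive array (camera adjusted p = 1.05e-07; adjusted p = 0.175 with an estimated correlation). The bound for KRT16 is that of the chosen probe, and its other detected probe differed by only 0.96. Epithelial junction genes rose in 8 of 24 cases, with E-cadherin CDH1 at 0.81, JUP at 0.91 and CLDN3, detected on 2 sensitive arrays, at least 1.65-fold higher (camera adjusted p = 0.0121; adjusted p = 0.255 with an estimated correlation). Integrin and basement membrane genes rose in 5 of 19 cases, with ITGAV at 1.04, ITGB1 at 0.61 and THBS1 at 1.58 (camera adjusted p = 0.0126; adjusted p = 0.255 with an estimated correlation). ITGB1 lies in a stretch of chromosome 10 in which 7 of 8 measured genes rose, itself included. Of the mesenchymal transition genes, 3 of 8 rose and 1 fell, the list was not past the threshold (camera adjusted p = 0.253), and VIM differed by -0.10 (adjusted p = 0.403). Replication-dependent histone genes rose in 16 of 24 cases and fell in 1, led by H2BC5, H2BC12 (2.26) and H2AC18 (1.65) (camera adjusted p = 5.36e-09; adjusted p = 0.175 with an estimated correlation). Members of this family are near-identical, so single histone genes are uncertain. Among the DNA replication genes, 3 of 31 rose and 3 fell (camera adjusted p = 0.936); their mean of 0.01 and the downward direction of camera differed in sign. Of the G2/M genes, 3 of 32 rose (KIF23 at 0.40, UBE2C at 0.37 and TOP2A at 0.23; camera adjusted p = 0.0435; adjusted p = 0.606 with an estimated correlation). Only 2 rose when adjusted over the list alone, and fry did not call the list (adjusted p = 0.149). Its share of risen genes did not exceed that of all genes, 1981 of 12495. UBE2C lies in a stretch of chromosome 20 in which 6 of 7 measured genes rose, itself included. Of the granzyme and complement regulators, 5 of 11 rose, with CFB at 1.32 and SERPINB1 at 0.81 (camera adjusted p = 0.0454; adjusted p = 0.255 with an estimated correlation). CD55 rose by 0.38 (adjusted p = 0.0222) and CD59 differed by 0.07 (adjusted p = 0.793), and SERPINB9, the granzyme B inhibitor, was not detected. RAET1G, CFB, H2AC18 and CD55 were each detected on 5 of the 6 sensitive arrays.

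The lists shifted down were those of secretory stress, sterol synthesis, chaperones and ribosomes. Of the endoplasmic reticulum (ER) stress and amino acid response genes, 14 of 30 fell and 3 rose (16 and 3 adjusted over the list alone). The serine synthesis enzyme PSPH, which lies near EGFR, and the ER genes CRELD2 (-1.16), SDF2L1 (-1.11) and PDIA4 (-0.56) fell (camera adjusted p = 0.000131; adjusted p = 0.175 with an estimated correlation). CRELD2 and SDF2L1 lie in stretches of chromosome 22 that were picked for their falling genes. In these stretches 16 of 18 and 6 of 7 measured genes fell, CRELD2 and SDF2L1 included. For PSPH, CRELD2 and SDF2L1, a shift of the list cannot be told apart from a shift of their neighbourhood. Of the cholesterol biosynthesis genes, 8 of 24 fell and 1 rose, with DHCR7 at -0.65 and CYP51A1, detected on 3 resistant arrays, at least 1.30-fold lower (camera adjusted p = 0.00708; adjusted p = 0.411 with an estimated correlation). Of the heat shock genes, 6 of 16 fell, with HSPB1, HSPA4L (-0.50) and BAG3 (-0.40) among them (camera adjusted p = 0.0217; adjusted p = 0.408 with an estimated correlation). HSPB1 carried much of the mean of -0.44 of this list, whose median was -0.10. It lies in a stretch of chromosome 7 in which 13 of 14 measured genes fell, itself included. The median of that stretch was -0.44, so HSPB1 fell far more than most of its neighbours. Of the ribosomal protein genes, 13 of 75 fell and 3 rose (11 and 2 adjusted over the list alone), with a mean of -0.08 (camera adjusted p = 0.0416; adjusted p = 0.411 with an estimated correlation). The remaining lists were not called by camera. Among the lists that camera did not call, fry, which does not compare a list with other genes, called ERK pathway targets downward (adjusted p = 0.0212) and p53 targets (0.0166), death receptor and apoptosis genes and the mitochondrial respiratory chain (0.00784 each) upward. It also called the NK receptor ligands (2.27e-05) and the mesenchymal transition genes (0.00784) upward and the ERBB list (0.0395) downward. Of the targets of the ERK pathway, which acts downstream of EGFR, 10 of 23 fell and 5 rose, with SPRY1 at -1.17, SPRY4 at -1.11 and DUSP6 at -1.05 (camera adjusted p = 0.0883). Of the death receptor and apoptosis genes, 7 of 34 rose and 3 fell, with BIK at -1.08 and CFLAR at 0.54 (camera adjusted p = 0.242). BIK lies in a stretch of chromosome 22 in which 24 of 27 measured genes fell, itself included. FAS differed by -0.15 (adjusted p = 0.329), TNFRSF10A by -0.23 (adjusted p = 0.0771) and TNFRSF10B by 0.16 (adjusted p = 0.161). The camera adjusted p was 0.349 for glycolysis and hypoxia (10 of 30 rose, 8 fell), 0.521 for p53 targets (3 of 21 rose, with CDKN1A at 1.57, and 2 fell) and 0.555 for NRF2 and oxidative stress (6 of 25 rose, 7 fell). It was 0.936 for immediate early genes (3 of 21 rose, 2 fell), whose mean of -0.08 differed in sign from the median of 0.03 and the upward direction of camera, and 0.0673 for the mitochondrial respiratory chain (10 of 47 rose, 6 fell).

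Transcripts of the effector cells were looked for in the same way. Of 33 NK cell markers, 28 were not detected on any array, GNLY, NKG7, PRF1, GZMB and GZMA among them, and the 2 that passed the filter (CST7 and TBX21) did not differ past the threshold (camera adjusted p = 0.936). Of 24 pan-leukocyte markers, 8 passed the filter, of which CD52 (at least 1.47-fold, detected on 2 sensitive arrays) and HCLS1 (0.51) rose and RAC2 (-0.34) fell (camera adjusted p = 0.686); PTPRC and CD53 were not detected on any array.

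**Figure D3:**
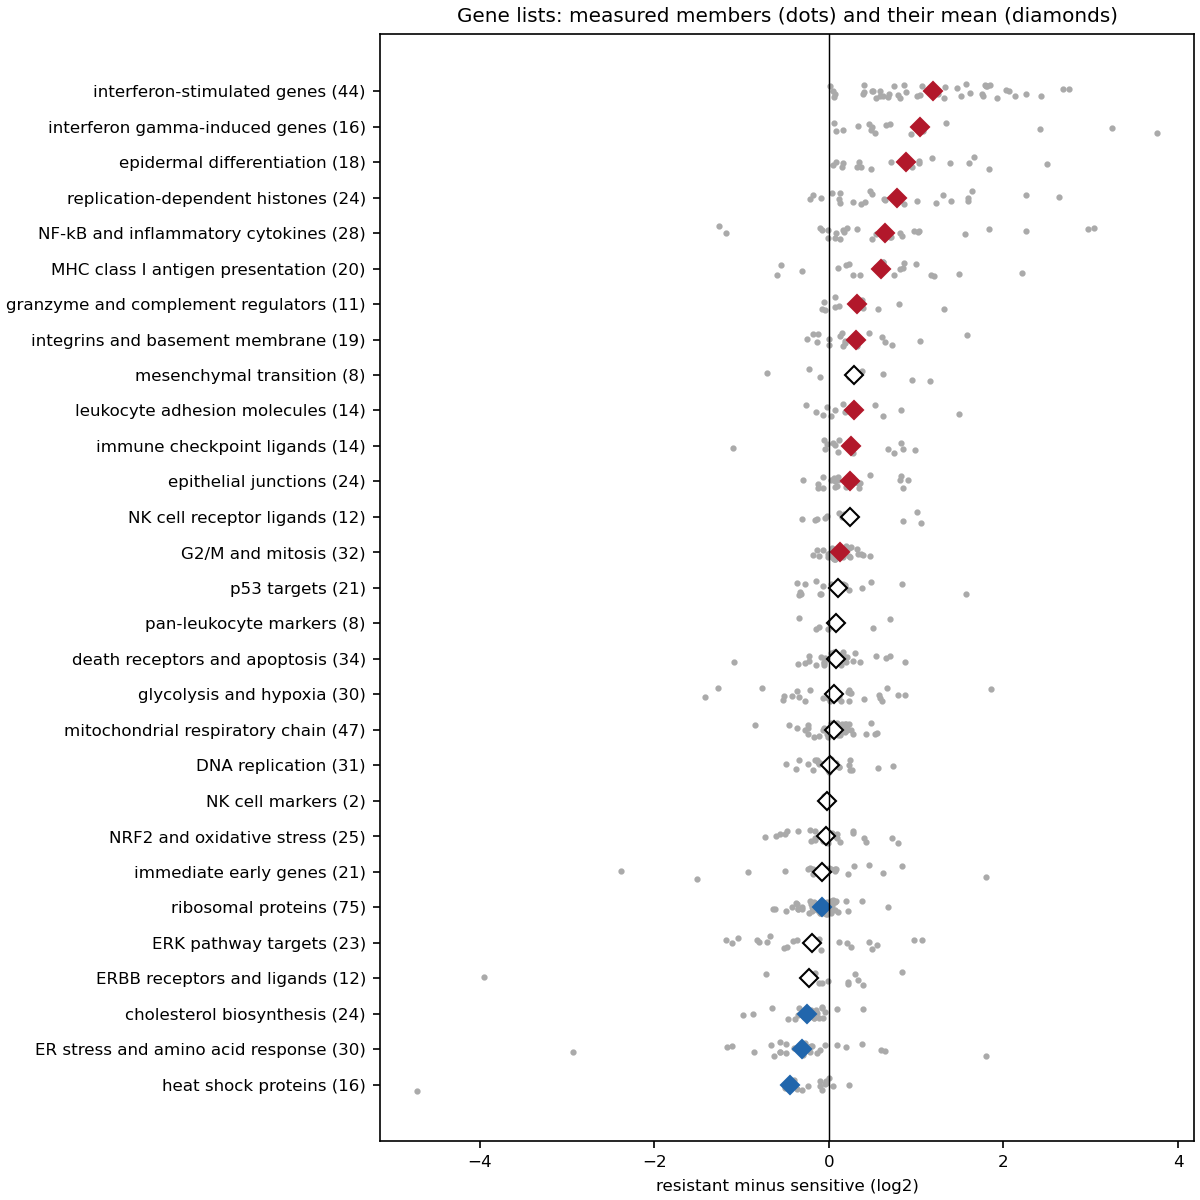
Difference in normalised log2 intensity, resistant minus sensitive, for the measured members of 29 gene lists (grey dots; vertical scatter is random; number of measured genes in parentheses) and the mean of each list (diamonds). Filled red and blue diamonds mark the 12 lists shifted up and 4 shifted down by camera with its preset correlation, none of which passed with an estimated correlation; interferon-stimulated genes had a mean of 1.19 and heat shock proteins one of -0.44, with a median of -0.10.

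The second question was how expression moved over the time labels. In resistant cells, 1631 genes had a slope past the threshold from C30 to C35 (limma, adjusted p under 0.05), 732 upward and 899 downward. The steepest falls were those of the immediate early genes FOS (-1.03 per time label, SE 0.19) and FOSB (-0.87), with the keratin KRT15 (-0.61), the interferon-stimulated gene OAS2 (-0.59) and CCL5 (-0.58) after them. The interferon-stimulated gene IFI44L was detected on only 4 of the 6 resistant arrays and fell by at least 0.58 per time label, with values under the lowest detected signal raised to it. Without the resistant C30 and C31 arrays, the slopes of FOSB (0.31) and KRT15 (0.41) turned upward and those of FOS (-0.10), IFI44L (-0.13) and OAS2 (-0.32) no longer passed, while CCL5 (-0.59) still did. The steepest rises were those of the transglutaminase TGM2 (0.43, SE 0.06), TMEM158 (0.40), IL32 (0.38), the non-coding SFTA1P (0.37), the cytokine CSF2 (0.35) and SLC43A3 (0.32). Of these rises, none passed without the resistant C30 and C31 arrays, where the slopes were 0.45 for TGM2, 0.10 for TMEM158, 0.23 for IL32, 0.15 for SFTA1P, 0.04 for CSF2 and 0.00 for SLC43A3. Without the resistant C30 array alone, FOS (-0.85), FOSB (-0.60), IFI44L (-0.68), KRT15 (-0.28), CSF2 (0.27) and SLC43A3 (0.23) lost their call and SFTA1P passed at 0.18; FOSB (-0.74) and KRT15 (-0.55) also lost it without C31, and KRT15 (-0.63) without C34. Of the interferon-stimulated genes, 35 of 44 fell and 0 rose (41 fell adjusted over the list alone), with a mean slope of -0.30 per time label (camera adjusted p = 2.47e-26; adjusted p = 0.309 with an estimated correlation). Of the other lists, 8 passed camera and none with an estimated correlation (lowest adjusted p = 0.309). Interferon gamma-induced genes (11 of 16 fell), MHC class I genes (10 of 20), histones (7), immediate early genes (6) and epidermal differentiation genes (6, with 1 that rose) shifted down, and DNA replication, heat shock and ribosomal protein genes shifted up. EGFR had a slope of -0.16 per time label (adjusted p = 0.0285). Of the 617 genes that passed both here and between the groups, 503 moved back toward the sensitive level and 114 moved away from it. The early resistant arrays carried much of this trend: 179 genes passed without the resistant C30 array, 1050 without C31 and 29 without both, the last a choice made after seeing the data; array weights gave 626. With median scaling, 54.9% of the genes called rose, against 44.9% with quantile normalisation.

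In sensitive cells, 0 genes had a slope past the threshold with limma (lowest adjusted p = 0.449), and 950 passed at an unadjusted p under 0.05, where 625 are expected by chance. The joint fit gives both groups the same residual spread, so slopes had equal SEs in both (0.19 for FOS). Without the resistant C30 and C31 arrays, 1244 sensitive slopes passed unadjusted. Whether the groups differ in spread was not tested, so the counts of 1631 and 0 do not by themselves show different trends. FOS (-0.55 per time label) and FOSB (-0.43) had the same sign as in resistant cells and did not pass (adjusted p = 0.540 and 0.665). Of the lists, 2 shifted down with camera: immediate early genes, with a mean of -0.14, and interferon-stimulated genes, with a mean of -0.08 (adjusted p = 1.53e-05 each; adjusted p = 0.964 with an estimated correlation for both).

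Whether the trends differed between the groups was tested directly. The slope difference passed the threshold for 6 genes, all lower in resistant cells: CCL5 (-0.59 per time label, SE 0.08, adjusted p = 0.0201), MXD1 (-0.31), ZNFX1 (-0.30), CSAG3, CSAG1 and ID2. In sensitive cells CSAG3 and CSAG1 were not detected on any array and ID2 on 1, so a fall could not have been seen there. For these 3 genes the test shows a fall in resistant cells (-0.51, -0.40 and -0.33) and not that the groups differ in trend. CCL5 was limited in a similar way. Its mean in sensitive cells was 5.01, little above the mean of the lowest detected signals, 4.55. A fall as steep as in resistant cells (-0.58 per time label) could not have been seen there. The sensitive slope of CCL5, 0.006, shows only the absence of a small fall. CSAG3 and CSAG1 are neighbouring cancer-testis antigen genes, ID2 is an inhibitor of basic helix-loop-helix factors, MXD1 is an antagonist of MYC and ZNFX1 is an interferon-induced RNA sensor. The adjusted p of all but CCL5 lay between 0.0411 and 0.0457, and with the time label as a block 18 genes passed. The count was 0 without the sensitive C30, C31, C34 or C35 array, 1 without the sensitive C32 or C33 array, 2 without the resistant C31 array and 332 without the resistant C35 array, so it rests on single arrays. Without the resistant C30 and C31 arrays, 8 genes passed, and 0 of the 6 named here were among them.

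Of the 29 lists, 8 had a slope difference past the threshold with camera, 5 downward and 3 upward; none passed with an estimated correlation (lowest adjusted p = 0.370) or with fry. Interferon-stimulated genes had the lowest p by camera at the preset correlation, with a mean of -0.22 per time label (camera adjusted p = 2.34e-20; adjusted p = 0.381 with an estimated correlation). For 0 of its 44 genes did the slope difference pass over all genes, and for 21 it did, downward, when adjusted over the list alone. In resistant cells the list stood 1.85 above the sensitive mean at C30 and 2.10 at C31, and between 0.58 and 1.20 from C32 to C35. Interferon gamma-induced genes (-0.22; adjusted p = 0.370 with an estimated correlation), with 10 of 16 passing over the list alone, shifted the same way. So did MHC class I genes (-0.09; adjusted p = 0.370 with an estimated correlation), histones (-0.09; adjusted p = 0.370 with an estimated correlation) and epidermal differentiation genes (-0.12; adjusted p = 0.531 with an estimated correlation). DNA replication genes (0.06; adjusted p = 0.476 with an estimated correlation), heat shock genes (0.06; adjusted p = 0.476 with an estimated correlation) and ribosomal protein genes (0.03; adjusted p = 0.531 with an estimated correlation) shifted upward. Over the genes detected on all 12 arrays, the mean slope difference was -0.21 for 36 interferon-stimulated, -0.22 for 9 interferon gamma-induced and -0.05 for 9 epidermal differentiation genes, so genes near background carried much of the last. With the resistant C30 and C31 arrays left out, 5 lists passed, of which 0 were among these 8.

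**Figure D4:**
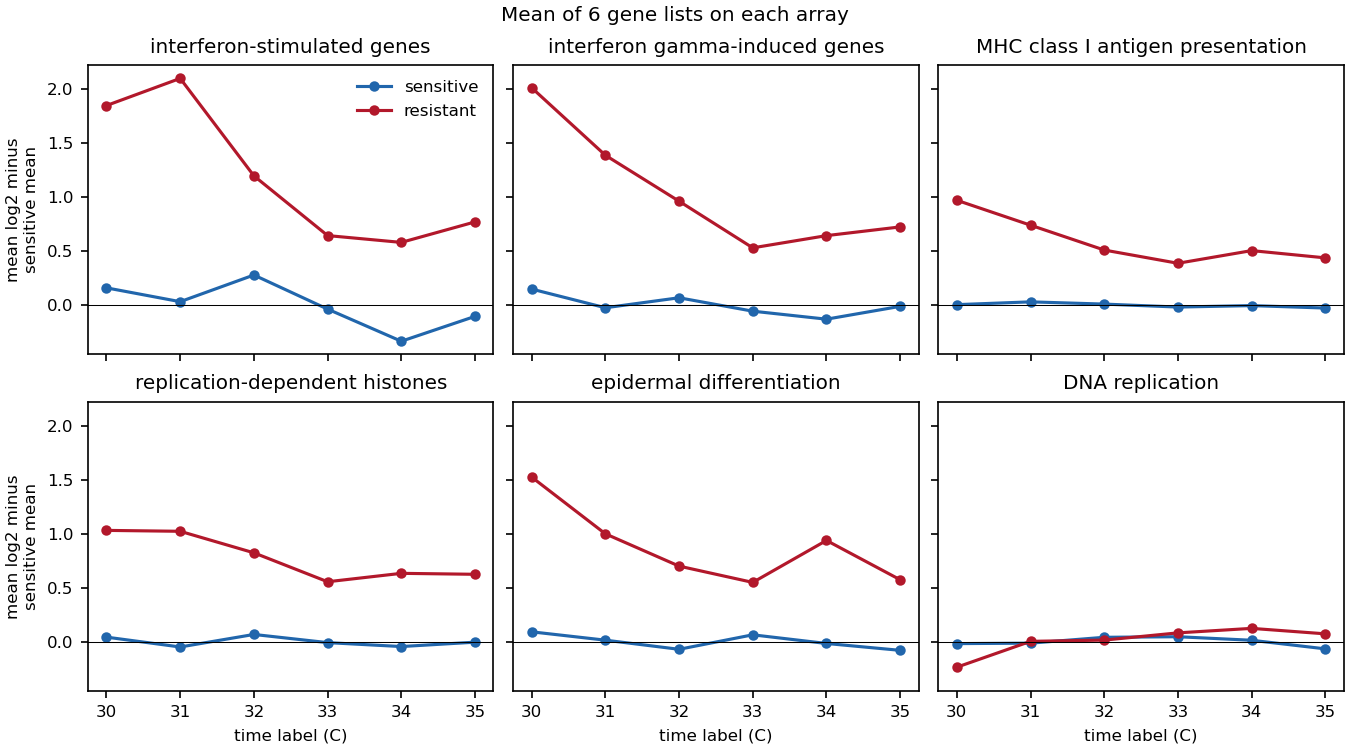
Mean of the measured genes of 6 lists on each array, as log2 difference from the mean of the 6 sensitive arrays, against the time label; blue lines are sensitive and red lines resistant cells. In resistant cells the interferon-stimulated genes stood at 1.85 and 2.10 on the first arrays and at 0.77 at C35, while the DNA replication genes stayed between -0.24 and 0.12.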

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

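All tests of explanations in this part were chosen after the results had been seen. Beyond the comparisons above, 3 kinds of result were looked at more closely. They were single arrays far from their group, trends with a called difference between the groups, and probes without a gene name.

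Values far from the other 5 arrays of a group occurred in 6 of 94 groups (47 named genes in both cell populations), where the Dixon test, which singles out 1 in 20 by chance, gives about 4.7. IFI27 stood at 9.26 in sensitive cells at C32, against at most 7.87 elsewhere in that group. PADI3 stood at 5.25 in resistant cells at C30, above the other 5 arrays (4.31 to 4.54), and CD55 at 4.88 on the same array, below the others (5.25 to 5.46). PSPH stood at 5.30 in resistant cells at C31, CD59 at 4.97 in sensitive cells at C35 and IRF1 at 7.68 in sensitive cells at C34, each the lowest of its group.

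The slope difference passed for 6 genes and 8 lists. The slope differences, resistant minus sensitive per time label, were -0.59 for CCL5, -0.31 for MXD1 and -0.30 for ZNFX1. For CCL5 the mean in sensitive cells was 5.01, little above the mean of the lowest detected signals, 4.55. A fall as steep as in resistant cells (-0.58) could not have been seen there, so its value does not show that the groups differ in trend. The computed values of -0.52 for CSAG3, -0.43 for CSAG1 and -0.32 for ID2 say nothing of sensitive cells, in which these genes were at background and had no room to fall. The list means were -0.22 for interferon-stimulated and for interferon gamma-induced genes, -0.0917 for MHC class I, -0.0907 for histone genes, -0.12 for epidermal differentiation, 0.0609 for DNA replication, 0.0578 for heat shock and 0.0266 for ribosomal protein genes. When the group labels were swapped within time labels in all 32 distinct ways, 5 gave at least the 6 genes observed, the real one included, and the highest other gave 3866. The largest counts came from swaps of late time labels, which carry the difference between the groups into the slopes, so this count reflects the structure of the samples and does not speak to chance. After the group means had been removed, only the real assignment, 1 of 32, reached 6 genes and the highest other gave 4, a narrow margin for a count that fell to 0 with the authors' values, so chance is left open. For the lists, 19 of the 32 swaps gave at least 8 lists (highest other 14), and 20 did with the group means removed (highest other 12), so chance is not excluded for the number of lists.

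For the comparison of the groups itself, 1 of 100 splits of the 12 arrays, the real one, gave as many as 3905 genes, and the highest other gave 1, so the arrays part by group. The splits treat the arrays as exchangeable, which successive samples of a single culture per group would not be. They cannot separate resistance from a difference between single cultures. Among the 10 drawn splits that part every pair of time labels, the highest other also gave 1. For the number of lists, the real split again was the only 1 of 100 to reach 16, but the highest other gave 15 and the median of the others was 7, so a single list past camera's preset threshold carries little weight.

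Among 611 detected probes with no gene name, 72 differed between the groups (27 higher and 45 lower in resistant cells), of which 2 by at least 1 log2 unit. Their share of 11.8% lay below the 31.3% of the 12495 genes that passed. The unnamed probes entered no comparison by gene.

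The fall of EGFR together with its neighbours was weighed first. Dilution of tumour RNA by RNA of the effector cells would lower epithelial genes alike, but the epithelial junction list had a median of 0.15 and none of its 24 genes fell. A lower level of EGFR transcripts alone does not cover the pattern either, since the 10 measured genes nearest to EGFR, 5 on each side and whatever their change, had a median of -1.07, against -0.24 for chromosome 7 outside the run. A loss of copies of a segment that holds EGFR needs its neighbours to fall together: of all groups of 10 neighbouring genes, 0.1415% (14 of 9894, 5 of them away from EGFR) had a median as low. Since the fall of these neighbours is what drew attention to them, this share does not count in favour of fewer copies; that explanation stays open as a hypothesis, for a line known to carry extra copies of EGFR, and copy number was not measured.

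The interferon programme, high in resistant cells and lower at later time labels, was weighed second. RNA of effector cells would bring their abundant transcripts, but 0 of 6 such transcripts (GNLY, NKG7, PRF1, GZMB, PTPRC and CD53) were detected on any resistant array, while 36 interferon-stimulated genes rose. The position on the chip, which runs with the time label, could lower the list in both groups: its slope was -0.30 in resistant and -0.08 in sensitive cells. With the group means removed, the difference of -0.22 had an exact p of 0.0625 under the 32 swaps, where 0.0312 is the smallest possible. The difference did not pass, so an effect of position stays open, and since position runs with the time label position and time cannot be told apart within a group. A response to the effector cells that weakened over the course stays open and untested.

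The rise of histone genes was weighed last. More cells in S phase would raise DNA replication genes too, but at 6 of 6 time labels that list differed by less than 0.25 times the histone list (0.99 against -0.22 at C30, 0.63 against 0.14 at C35). Signal shared between near-identical histone genes cannot be told apart from a rise of each: the estimated correlation within the list was 0.27, neither near 0 nor near 1, and the probe sequences were not compared here. A difference in the processing or tails of histone transcripts could also raise the signal and was not tested.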

How the results depend on the processing

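Leaving out the resistant C30 and C31 arrays was chosen after seeing the data; all other settings were planned. The count between the groups (3905) stayed between 2627 and 4694 except with C33 to C35 only (2280, on 6 arrays). EGFR kept its direction and call, from -4.19 to -3.35, except at the undetected probe for NM_201282.1 (-0.0562); other probes gave -2.17 and -5.45. The sensitive trend stayed at 0 genes under all settings, and the list count between the groups fell to 0 with an estimated correlation. The resistant trend (1631) gave 626 with array weights and 29 without the resistant C30 and C31 arrays. The slope difference (6 genes) gave 1 with median scaling, 0 without background correction, 2 with offset 50, 0 with the authors' values, 1 without a filter, 2 with detection on all 12 arrays, 13 with a trended robust prior, 2 with array weights and 18 with the replicate block; without the resistant C30 and C31 arrays it gave 8, of which 0 were among the 6. Its 8 lists became 0 with an estimated correlation, 0 with fry and 5 without the resistant C30 and C31 arrays. The cause was not tested for any of these beyond the smaller number of arrays where some are left out. With single arrays left out, counts ranged from 3382 to 4028 between the groups, from 179 to 2322 for the resistant trend, from 0 to 0 for the sensitive trend and from 0 to 332 for the slope difference; EGFR ranged from -4.05 to -3.85, and the lists from 12 to 16 and from 7 to 9. With the replicate block, 4431 genes and 16 lists differed between the groups and 9 lists in slope. For the ERBB list, fry gave a downward direction (adjusted p = 0.0395) and camera an upward one, with the same list mean of -0.23. Reversed values without the resistant C30 and C31 arrays were slopes of 0.31 for FOSB and 0.41 for KRT15 in resistant cells. Slope differences of lists also reversed there, to 0.0242 for epidermal differentiation, 0.0532 for glycolysis and hypoxia, 0.20 for immediate early genes and -0.0054 for ribosomal proteins. Of 1183 values of named genes between the groups under other settings, 1152 kept direction and call; of 262 resistant slopes, 238 did, and of 135 slope differences, 48. Dim genes limit the comparison, since between 14648 and 15987 of the 47323 probes stood above background on an array.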

Other observations

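The tests in this part were chosen after the results had been seen. Genes that changed between the groups were not spread evenly over the chromosomes. Chromosome 7 had 233 of 460 measured protein-coding genes lower in resistant cells (50.7%) and 20 higher, and outside the run that holds EGFR it was still 221 of 448 (49.3%), against 15.01% over all chromosomes. The genes of chromosome 7 included HSPB1, within a stretch from POM121C to TMEM60 in which 13 of 14 fell, itself included, and SGCE, within a stretch from BET1 to ASNS in which 7 of 8 fell. The medians of these stretches were -0.44 and -0.48. HSPB1 (at least 25.03-fold lower) and SGCE (at least 5.86-fold lower) fell furthest in them, so a shift of the size of the medians would not cover their fall. On chromosome 22, 24 of 27 genes from XRCC6 to FAM118A fell, with a median of -0.76, and 16 of 18 from BRD1 to SCO2. On chromosome 14, 15 of 16 genes from BBOF1 to FOS fell, with a median of -0.93. On chromosome 3, 220 of 590 genes rose (37.3%) and 21 fell, and all 9 measured genes from RAB5A to TOP2B rose. Local clusters of related genes rose as well: 6 of 6 histone genes on chromosome 1 from H4C14 to H2AC20, 9 of 10 genes from HLA-DRA to RXRB on chromosome 6 and 6 of 7 from KRT13 to JUP on chromosome 17. Near-identical histone genes are counted apart here. The stretches named in this part were picked where windows of 7 neighbours held at least 6 genes that changed one way. Their ends were trimmed to such genes, so the high share within a stretch restates the choice.

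A window scan put numbers on this. Among 10124 genes in reference order, 146 windows of 7 genes held at least 6 that fell, against a mean of 0.711 and at most 8 after shuffling the genes, and 31 windows held at least 6 that rose, against a mean of 1.95 and at most 18. Both had a permutation p = 0.001, the smallest that 1000 shuffles can give, and neighbouring windows overlap. The median differences of 4 chromosomes lay outside the shuffled range of -0.09 to 0.12: chromosomes 7 (-0.25), 22 (-0.17), 10 (-0.14) and 3 (0.17). Chromosome 10 did not shift as a whole: 6 of 7 genes from PFKP to CALML5 and 7 of 8 from WAC to ITGB1 rose, while 9 of 10 from MCU to CHCHD1 fell. Chromosome 14, despite its falling stretches, had a median inside the range (-0.06). A candidate explanation is a different number of copies of chromosomes, arms or segments in the 2 cell populations, in addition to the segment around EGFR. It stays a hypothesis, since the medians restate the shifts that prompted it. Shared regulation of neighbouring genes could give local runs too and was not separated from it, and copy number was not measured in these samples. No sample from before the exposure is among these arrays, so when such a difference arose was not tested.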
